A study of Anolis sagrei with 40 samples.

How the data were processed

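DNA methylation was measured by enzymatic methyl sequencing in blood cells of the brown anole, Anolis sagrei, a small lizard. In this assay unmethylated cytosines are converted by enzymes in place of bisulfite and are read as thymine, while methylated cytosines are read as cytosine. Per the labels' protocols, the animals were captive-bred with a recorded hatch date, trunk blood was spun to part plasma from cells, and DNA came from the cell pellet, which held mostly nucleated red blood cells. Libraries were made with the NEBNext Enzymatic Methyl-seq kit and sequenced on 2 lanes. The lane of each library was not given in the sources used here, so lanes could not be compared. The design text gives a target depth of 5x per animal.

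The submitters' processing notes name Trim Galore, cutadapt, FastQC, Bismark, SAMtools and methylKit, without versions or roles. The genome build and the minimum read depth for a value were not given in the sources used here. The authors deposited a single table with the percent methylation of 33,421,767 cytosines, one strand of a CpG each, in one column per animal. Columns whose values are recorded here under the unit "other" were deposited on the same percent scale from 0 to 100. Coordinates are those of the scaffolds in the deposited table, counted from 1.

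The table had columns for 37 of the 40 labelled animals. The animals 36mo Male replicate 2, 48mo Female replicate 2 and 7mo Female replicate 1 were not analysed here. No column of other samples was found (0 columns not used). The read depth behind each percentage is unknown, so values could not be weighted by depth, no counting interval could be given, and a low-depth value counts as much as a deep one. The number of cytosines with a value was taken as a stand-in for coverage. It ran from 1,023,780 to 18,440,287 per library, with a median of 11,766,586, and 35.6% of all table entries were filled. The libraries of 60mo Female replicate 3 and 36mo Male replicate 1 were sparse, with 1,023,780 and 2,270,090 cytosines, and the other 35, called the denser libraries here, had at least 6,701,586 each.

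The following choices were made before the data were examined: the models, the 5% threshold, the filters on sites and windows, the naming rule and most alternatives. A site was tested where at least 30 animals, 14 of each sex, had a value and the mean lay between 5 and 95%, which left 327,472 sites. The planned test on read counts needs counts, so the percentages were fitted by least squares, as had been foreseen for a file of percentages alone. Terms were age in months and sex, with the age by sex product added for the interaction and age alone within a sex. Variances were moderated as in limma, in Python code checked against limma 3.58.1 on 3,000 windows, with no difference in log10 p. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all features of a test. A change with age is the fitted slope times 59 months, the span from 1 to 60 months, in percentage points, and a sex difference is male minus female.

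No annotation of the table's build was at hand, so promoters were replaced by 1 kb windows, as had been foreseen. Gene bodies, gene lists, wider promoters and promoter-based age prediction were not run, and no gene is named. A window value was the plain mean of the sites in the window where an animal had at least 5. A window was tested where at least 36 animals had a value, which left 24,620 windows. No tested window therefore lacked a value in both sparse libraries, so these windows are places that thin libraries still cover and need not stand for the whole genome. A wider set of 165,131 windows, with a value in at least 34 animals and each site first expressed as its deviation from the site mean, was analysed as an alternative. That wider set had been chosen from coverage and was fitted first; the stricter windows, which are those of the written design, were made the primary set only after both counts had been seen. The wider set is therefore always named as an added alternative.

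Mean methylation per animal was the mean deviation from site means over 314,757 tested autosomal sites, added to the overall mean, and entropy was the mean Shannon entropy per site over the same sites. These were set against age by Pearson and Spearman correlation with permutation tests of 100,000 resamples, in a family of 6 relations. Differences between sexes were tested by permuting sex within age. Age was predicted by an elastic net (l1 ratio 0.5) on windows with a value in every animal, each animal predicted from a model trained on the others, with 5,000 windows kept per training set. Of the windows, 10,463 had a value in all 37 animals. Ages were permuted 24 times, so the smallest p this can give is 0.04. A longer series of permutations was shortened to keep within a time limit, after its result had been seen. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3.

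The naming rule took, for windows, the 12 largest rises and the 12 largest falls past the threshold for each test, and for sites the 5 with the smallest p in each direction. In simulations on the 24,620 windows, an age change of 5 points was called in 10.5% of 200 changed windows, one of 10 points in 48.5% and one of 20 points in 91.5%. For a sex difference the shares were 20.0%, 72.0% and 99.5%. Animals of a group are separate individuals, and replicate numbers only name them. Each animal belongs to a single age group, so a change with age compares different animals. The sample numbers in the titles ran in blocks by age. A hatch cohort or handling batch that followed these blocks cannot be told apart from age. The alternatives tried were log2 age, unmoderated variances, a minimum change of 10 points, other filters on sites and windows, leaving out the 1 or 60 month animals or the sparse libraries, an arcsine scale, centring of each animal, and leaving out each animal in turn.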

Results

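Blood cell methylation was measured in 37 brown anoles, 19 females and 18 males, at 6 ages. At 1 month there were 2 females and 2 males, at 7 months 4 and 5, at 18 months 3 and 3, at 36 months 4 and 2, at 48 months 3 and 3, and at 60 months 3 and 3. Each library had a percent methylation for between 1,023,780 and 18,440,287 cytosines, and the depth behind each value is unknown. Brown anoles have XX females and XY males. From 21,000,001 to 92,000,000 of scaffold_7, a segment of 71 Mb, the share of cytosines with a value relative to autosomes was 1.13 ± 0.0865 in females (SD, n = 18) and 0.372 ± 0.0457 in males (SD, n = 17), without the 2 sparse libraries. On the rest of scaffold_7 these shares were 0.940 ± 0.0719 and 0.930 ± 0.0427. The bounds of the segment were set from these shares, and results inside it are given apart.

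The first question was whether the mean methylation level of blood cells changed with age. It was lowest at 1 month, at 76.7% ± 1.81 (SD, n = 4), and stood at 79.9% ± 0.728 (n = 9) at 7 months and 80.1% ± 1.04 (n = 6) at 18 months. At 36, 48 and 60 months it was 79.2% ± 3.07, 81.2% ± 1.5 and 80.03% ± 2.67 (n = 6 each). Mean entropy per site, which is highest for sites near 50% methylation, fell from 0.602 ± 0.0288 bits at 1 month to 0.516 ± 0.0381 bits at 60 months. The mean level did not pass the test for a linear relation with age (Pearson r = 0.287, permutation p = 0.0847, adjusted p = 0.127), although the ranks did (Spearman rho = 0.471, permutation p = 0.00343, adjusted p = 0.0103, family of 6 relations). With all sites of each animal r was 0.0676 (permutation p = 0.702). Without 60mo Male replicates 1 and 2, 2 of the 6 animals of 60 months that lie equally far from the median age, r was 0.280; over all 15 pairs of these 6 it ran from 0.217 to 0.444. Without the sparse libraries of 60mo Female replicate 3 and 36mo Male replicate 1, an alternative added after the data were seen, r was 0.565 (permutation p = 0.00021). Leaving out either one alone also brought it past the threshold, with r = 0.430 without 60mo Female replicate 3 and r = 0.369 without 36mo Male replicate 1. Without the 4 animals of 1 month, also added after the data were seen, r was 0.0880 (permutation p = 0.634).

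Within the sexes, mean methylation and age had r = 0.289 in 19 females (permutation p = 0.238, rho = 0.509) and r = 0.281 in 18 males (permutation p = 0.273, rho = 0.510). The adjusted p-values of the ranks were 0.0378 in both sexes. Over both sexes, entropy and age had r = -0.458 (permutation p = 0.0044, adjusted p = 0.0264) and rho = -0.501 (permutation p = 0.00186, adjusted p = 0.0103). Without 60mo Male replicates 1 and 2 r was -0.452, over all 15 pairs it ran from -0.537 to -0.377, and without the 1 month animals, an added alternative, it was -0.290 (permutation p = 0.101). Within females r was -0.468 and within males -0.448 (adjusted permutation p = 0.123 each). The rho values were -0.474 and -0.544 (adjusted permutation p = 0.0423 and 0.0378). In the 35 denser libraries, an added alternative, entropy also rose with log2 of the number of cytosines with a value (r = 0.368, permutation p = 0.0292). Given that number, entropy and age had r = -0.605 there (permutation p = 0.0001). Mean methylation was 80.01% ± 2.30 in females and 79.4% ± 2.01 in males. The male minus female difference within ages was -0.651 points (permutation p = 0.320). It was -0.142 points without 36mo Male replicate 1 (permutation p = 0.812), -1.03 without 60mo Female replicate 3 (permutation p = 0.0541) and -1.35 with all sites of each animal (permutation p = 0.359), and no setting passed the threshold.

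**Figure D1:**
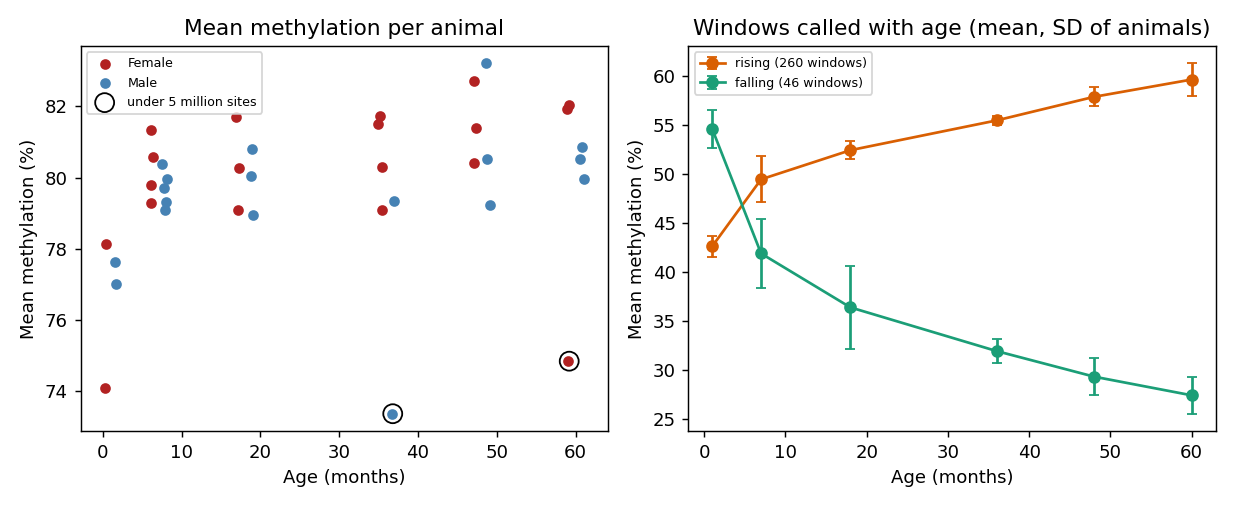
Left, mean methylation (%) of each animal against age in months, females red and males blue, with the 2 sparse libraries circled. Right, mean methylation of the windows called with age, in the 35 other libraries, as mean and SD of animals per age; the rising windows went from 42.7% at 1 month to 59.7% at 60 months and the falling windows from 54.6% to 27.5%.

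The next question was which regions changed with age. Of 24,620 windows of 1 kb, 306 changed at an adjusted p under 0.05 by the limma test, 260 rising and 46 falling, so that 85.0% of the calls rose. Changes in points are slopes fitted over all ages and percentages are group means, so a change can differ from the gap between means. The strongest rise by p was at scaffold_1, 141666001 to 141667000, which rose by 47.1 points over 59 months (SE 4.57, adjusted p = 6.26e-08), from 3.97% ± 2.19 at 1 month (n = 4) to 51.7% ± 11 at 60 months (SD, n = 6). A run of 4 neighbouring windows on scaffold_2, 178875001 to 178879000, rose by 43.9 points on average. Its window starting at 178876001 showed the largest rise of all windows called, 51.7 points (SE 7.60), from 7.27% at 1 month through 27.8% at 7 months to 66.8% at 60 months. The largest fall was at scaffold_10, 36711001 to 36712000, where methylation fell by 43.7 points (SE 6.58, adjusted p = 0.000341), from 78.7% ± 3.31 to 25.5% ± 10.4 (SD, n = 5 at 60 months).

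Among the other named rises were 3 windows of scaffold_3. The window starting at 200985001 rose by 47.8 points, from 13.8% to 85.5%. That at 200922001 rose by 41.9 points, from 21.3% to 90.1%, and that at 200938001 by 35 points, from 20.5% to 62.6%. On scaffold_1 the windows starting at 141655001, 315742001 and 266346001 rose by 43.2, 40.7 and 40.5 points. The window at 90883001 of scaffold_6 rose by 40.3 points, from 9.41% to 60.5%. The remaining members of the scaffold_2 run, starting at 178875001, 178878001 and 178877001, rose by 44.4, 42.2 and 37.5 points.

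Among the other named falls, the window starting at 206018001 of scaffold_5 fell by 40.4 points, from 74.1% to 24.9%. The window at 102849001 of scaffold_6 fell by 38 points, and most of its fall was already present at 7 months, with means of 71.4% at 1 month, 32% at 7 months and 15.9% at 60 months. On scaffold_10 the window at 15895001 fell by 32.6 points, with 54.9% at 1 month, 58.1% at 7 months and 22.7% at 60 months. The windows at 26426001 of scaffold_8 and 9185001 of scaffold_7, which lies outside the segment, fell by 30.2 and 29.1 points. On scaffold_4 the windows at 53232001 and 169108001 fell by 28.4 and 26.9 points, the latter from 39.6% to 4.14%. The windows at 3985001 and 11827001 of scaffold_12 each fell by 26.4 points. Those at 69682001 of scaffold_1 and 6855001 of scaffold_13 fell by 26.1 and 25.9 points.

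**Figure D2:**
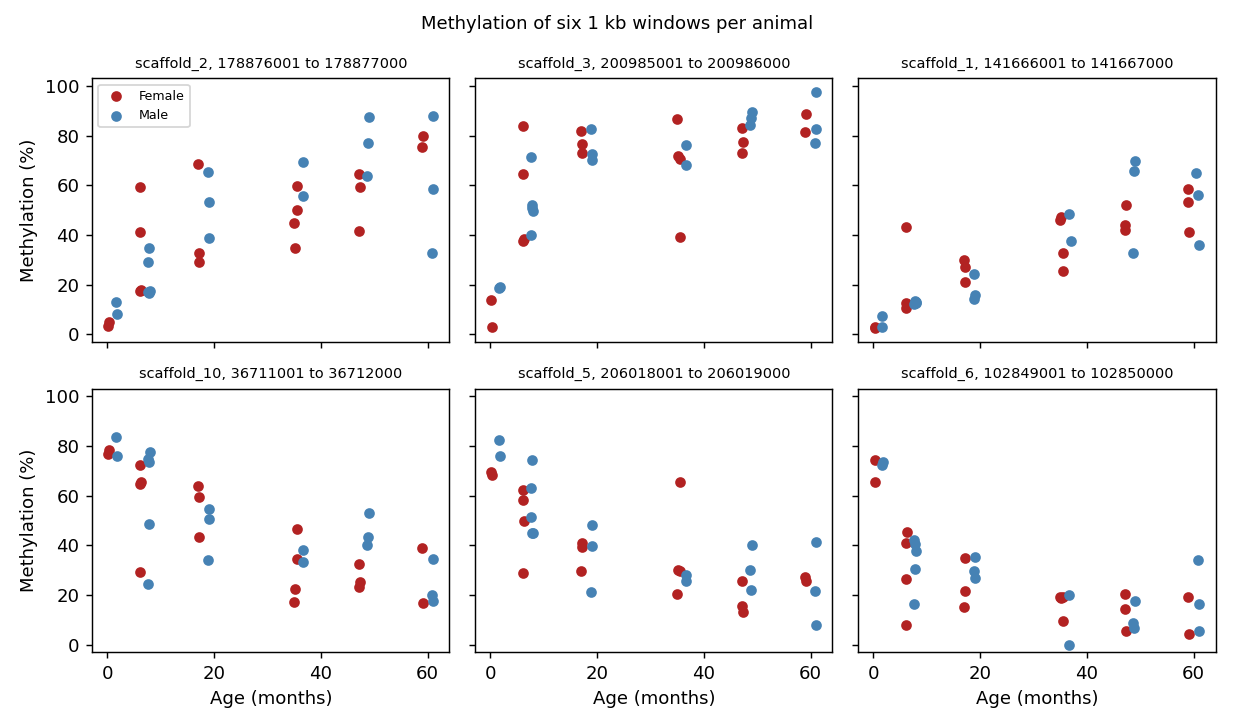
Methylation (%) against age in months of the 3 windows with the largest rise and the 3 with the largest fall among those called, one point per animal, females red and males blue. At scaffold_1, 141666001 the mean went from 3.97% at 1 month to 51.7% at 60 months, and at scaffold_10, 36711001 from 78.7% to 25.5%.

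The called windows merged into 289 regions, of which 14 held at least 2 windows, and in 0 of these did rising and falling windows mix. Windows of intermediate methylation, between 20 and 60%, were called most often, in 4.07% of 1,303 windows (95% block jackknife interval 2.86 to 5.28), and 54.7% of those calls rose. The block jackknife leaves out blocks of the genome and keeps all animals, so its intervals do not measure the spread between animals. The class of a window rests on its mean over the same animals, so a large change tends to place it in the middle class. Windows under 20% were called in 2.87% of cases (2.06 to 3.67), and 87.4% of these calls rose. Windows over 80% were called in 0.5% of cases (0.383 to 0.618), with 95.2% rising. In the wider set described below, an alternative added after the data were seen, 51.4% of 354 calls rose in windows under 20% (95% block jackknife interval 42.05 to 60.8) and 40.3% of 1,172 calls in windows between 20 and 60% (36.5 to 44.0), so that falls were the more frequent in the latter class. In the segment of scaffold_7, 1 of 351 windows was called with age. In the 35 denser libraries, the rising windows averaged 42.7% at 1 month, 49.5% at 7 months, 52.5% at 18 months, 55.5% at 36 months, 57.9% at 48 months and 59.7% at 60 months. The falling windows averaged 54.6%, 41.9%, 36.4%, 32%, 29.4% and 27.5%. By 7 months the rising windows had covered 40.1% of their change and the falling windows 46.7%, in windows that were picked for their relation with age.

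The count of windows changed with the scale of age, the animals left out and how windows were formed. It was 1,092 on log2 age, 180 with a change of at least 10 points, 127 without the 60 month animals and 661 without the sparse libraries. It was 22 without the 1 month animals, and 159, 166 and 181 without 1mo Female replicate 2, 1mo Female replicate 1 and 1mo Male replicate 1. It was 484 with deviations from site means, 2,182 with windows in at least 34 animals and 4,814 with both. With each animal centred on its own median shift, 115 windows were called and 57.4% of them rose, against 85.0% without centring. Across all 24,620 windows the median change was 1.67 points and 73.8% of changes were positive. A direct comparison of 9 animals of 7 months with 4 of 1 month called 56 windows by the limma test, 46 of them higher at 7 months, and 10 of the 56 were also called with age.

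At single cytosines the number and the direction of calls with age changed with the setting. Of 327,472 sites, 2 passed the adjusted threshold in the limma test and both fell. The site at 244750399 of scaffold_1 fell by 61.7 points (SE 8.80, adjusted p = 0.0194), from 79.9% at 1 month to 2.86% at 60 months. The site at 53234083 of scaffold_4, close to the falling window at 53232001, fell by 57.4 points (SE 8.84, adjusted p = 0.0499), from 75.0% to 0.0%. At an unadjusted p under 0.05 there were 23,793 sites. On log2 age 132 sites were called, 96 of them rising, and with sites in at least 20 animals, an added alternative, 1,176 were called, 394 rising and 782 falling. Without 1 animal in turn the count was 0 for 6 animals, 1 for 17, 2 for 6, 3 for 3 and 4 for 5.

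The series asks how age and sex act together, and within each sex fewer windows were called. In females the window at scaffold_1, 141666001 was the single call (41.5 points, SE 6.07, adjusted p = 0.0383, limma). In males 21 windows were called, 18 rising and 3 falling, and the same window was among them (52.5 points, SE 6.51, adjusted p = 0.00328). Other rises in males were at scaffold_2, 178878001 (56.6 points), scaffold_3, 200985001 (48.8 points), scaffold_4, 76239001 (44.2 points) and scaffold_6, 90883001 (42.2 points). The falls in males were at scaffold_7, 9185001 by -41.5 points, scaffold_4, 53232001 by -35.4 points and scaffold_4, 169108001 by -27.8 points. Independent lists of these sizes would share 0.0007 windows. At an unadjusted p under 0.05 there were 2,980 windows in females and 1,986 in males.

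The counts within a sex do not show a difference between sexes. The test of the difference itself called 0 windows by limma, with 1,136 windows at an unadjusted p under 0.05. In the 260 rising windows the median change was 10.3 points in females and 10.4 points in males, and in the 46 falling windows it was -18.0 and -20.5 points. The level of rising minus falling windows rose by 34 points over 59 months in females and by 35.8 points in males (permutation p = 0.658 for the difference). These windows were picked by the age test over both sexes, which favours like changes in females and males, so their likeness decides little. Over all windows, which are not independent, the slopes of females and males had a Pearson r of 0.248. The order of the counts turned on log2 age, with 293 windows in females and 75 in males. The female count was 52 and the male count 519 in the wider set of windows, and the count without single animals ran from 0 to 13 in females and from 3 to 40 in males.

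One site passed the interaction test, at 194704058 of scaffold_3. In females it went from 74.4% ± 19.0 at 1 and 7 months (SD, n = 5) to 9.05% ± 9.17 at 36 to 60 months (n = 7). In males it was 63.8% ± 5.67 (n = 7) at the young ages and 68.8% ± 13.7 (n = 8) at the old ages. The difference of the changes was 89.3 points (SE 12.5, adjusted p = 0.0139, limma), and 16,956 sites had an unadjusted p under 0.05. Without 1mo Female replicate 1 the count of such sites was 0, without 60mo Male replicate 1 it was 3, and without 48mo Male replicate 3, 60mo Male replicate 2 or 7mo Male replicate 2 it was 2. Within females and within males 0 sites were called with age by limma, with 22,952 and 17,664 at an unadjusted p under 0.05.

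Of the 25 windows called with sex, 9 lay in the scaffold_7 segment and 16 outside it, and the 4 largest differences lay at one place of the segment. Between 62450001 and 62568000, 118 kb, all 5 windows tested were called and lower in males, with the bounds of this place set from these calls. They were the only calls among the 11 windows tested from 62178001 to 62568000. At 62488001 to 62489000 females had 84.4% ± 4.91 (SD, n = 19) and males 20.3% ± 4.71 (n = 17), a difference of -64.0 points (SE 1.60, adjusted p = 1.38e-26, limma). The windows starting at 62491001, 62450001, 62567001 and 62487001 differed by -60.0, -50.6, -26.1 and -17.6 points. Averaged over these 5 windows in the 35 denser libraries, females had 87.6% ± 2.06 (n = 18) and males 44.0% ± 2.57 (n = 17), and the lowest female, at 80.6%, lay above the highest male, at 48.5%. Males had a larger share of cytosines with a value here, 29.4%, than in the rest of the segment, 14.6%, while females had 53.3% and 42.3%.

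At the single cytosines of this place named below, which were picked for the smallest p, the sexes were almost fully apart. This did not hold for most cytosines here: of those over 80% in females, 30.3% lay under 20% in males. The site at 62450515 had 97.3% ± 4.16 in females (n = 19) and 0.840% ± 3.47 in males (SD, n = 17), a difference of -96.5 points (adjusted p = 1.17e-32, limma). The sites at 62483897, 62485346, 62466222 and 62466395 differed by -93.2, -92.4, -92.4 and -91.0 points. Elsewhere in the segment, 4 sites between 44578400 and 44579406 were higher in males, among them 44579223 with 75.4% ± 17.5 (n = 17) against 38.3% ± 10.6 (SD, n = 17; adjusted p = 1.13e-05, limma). The window at 87381001 was also higher in males, 29.3% against 8.04%. The windows at 88924001, 89750001 and 44792001 were lower in males by -22.7, -7.52 and -6.03 points. In the whole segment 205 of 9,554 sites and 9 of 351 windows were called.

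**Figure D3:**
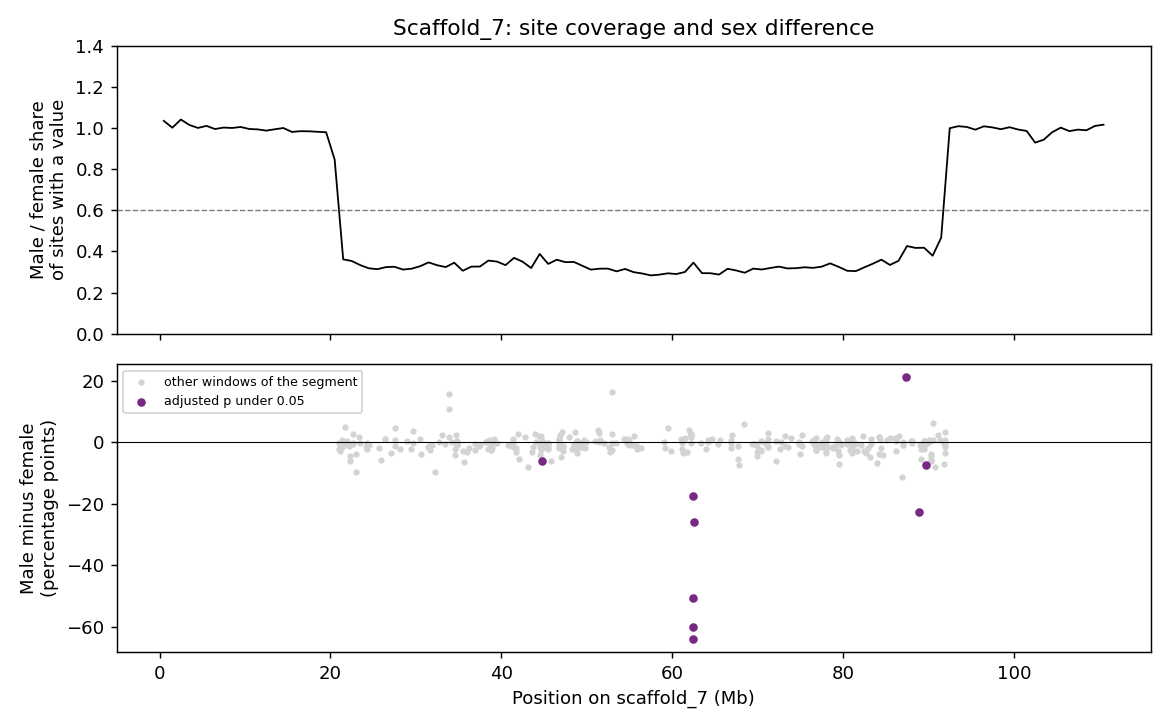
Top, male over female share of cytosines with a value along scaffold_7 per Mb, with a dashed line at 0.6. Bottom, male minus female methylation (percentage points) of each of the 351 windows tested in the segment, with the 9 called windows in purple; 5 of these lie between 62450001 and 62568000 and reach -64.0 points.

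Outside the segment, 16 windows were called with sex and all 16 were lower in males. The largest difference was at 34889001 to 34890000 of scaffold_10, with 74.1% ± 10.0 in females and 56.8% ± 7.39 in males (SD, n = 18 each; -17.2 points, SE 2.64, adjusted p = 0.000503). At 85990001 of scaffold_1 females had 87.7% ± 5.77 and males 72.5% ± 3.88 (-15.2 points, adjusted p = 6.91e-08). Neighbouring windows at 10034001 and 10035001 of scaffold_11 differed by -10.9 and -11.4 points. Windows at 30334001 of scaffold_5, 3612001 of scaffold_12 and 114462001 of scaffold_5 differed by -11.6, -9.85 and -9.54 points. On scaffold_2 a run of 4 windows was called, those at 139749001 and 139748001 by -8.85 and -8.61 points. The windows at 241713001 of scaffold_4, 303462001 of scaffold_1 and 39098001 of scaffold_6 differed by -8.80, -7.64 and -7.51 points. At these 16 windows males had a median of 1.192 times the female number of sites with a value, where random sets of matched windows gave 0.965 to 1.05.

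Of the sites outside the segment, 122 were called with sex, 24 higher and 98 lower in males. Reads of sex-linked copies were not tested for at these sites. Among those named below, 85990517 of scaffold_1 and 39098736 of scaffold_6 lay in called windows. There males had 2.11 and 1.113 times the female number of sites with a value. No other named site lay in a called window. With each animal centred on its own mean shift there were 119, and 34 of them were higher in males. The largest difference among the named sites was at 75621462 of scaffold_1, with 7.11% ± 11.2 in females (SD, n = 15) and 61.5% ± 11.9 in males (n = 17; 54.4 points, adjusted p = 3.05e-11, limma). Higher in males were also 194704062 of scaffold_3, 4 bases from the interaction site, by 42.8 points, 30335096 of scaffold_5 by 39 points, 137991806 of scaffold_1 by 32.9 points and 85995313 of scaffold_1 by 19.6 points. Lower in males were 215087396 of scaffold_3 by -39.05 points, 102581039 of scaffold_1 by -34.8 points, 39098736 of scaffold_6 by -34.3 points, 85990517 of scaffold_1 by -31.6 points and 194703441 of scaffold_3 by -29.5 points.

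The last question was how well age could be predicted and whether the sexes differed in predicted age. Each animal was predicted from the others with a median absolute error of 9.18 months, against 20 months when each animal was given the median age of the others and 17 months when all were given the median age of 18 months. Trained on log2 age, the prediction had an error of 3.71 months. The mean predicted age was 1.13 ± 1.79 months at 1 month (SD, n = 4), 19.9 ± 9.40 at 7 months (n = 9), 24.8 ± 5.11 at 18 months, 30.1 ± 8.96 at 36 months, 40.5 ± 7.05 at 48 months and 34.9 ± 8.05 at 60 months (n = 6 each). The animals of 7 months were thus predicted older and those of 60 months younger than they were. The lowest error of 24 permutations of the ages was 18.8 months (permutation p = 0.04, the smallest they can give). Predicted and actual age had r = 0.733 and rho = 0.768.

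Males were predicted younger relative to their age than females by -4.26 months (permutation p = 0.0897), which did not pass the test. The difference came past the threshold without 36mo Female replicate 2, at -5.13 months, and was -1.74 months without 7mo Female replicate 5. It was -1.71 months without the sparse libraries (permutation p = 0.537) and -1.49 months with deviations from site means (permutation p = 0.598), both added alternatives. On log2 age it was 0.265. Models trained on females had a median absolute error of 13.3 months in males, against 13.5 months in females left out in turn. Models trained on males had one of 9.58 months in females, against 7.85 months in males left out in turn.

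**Figure D4:**
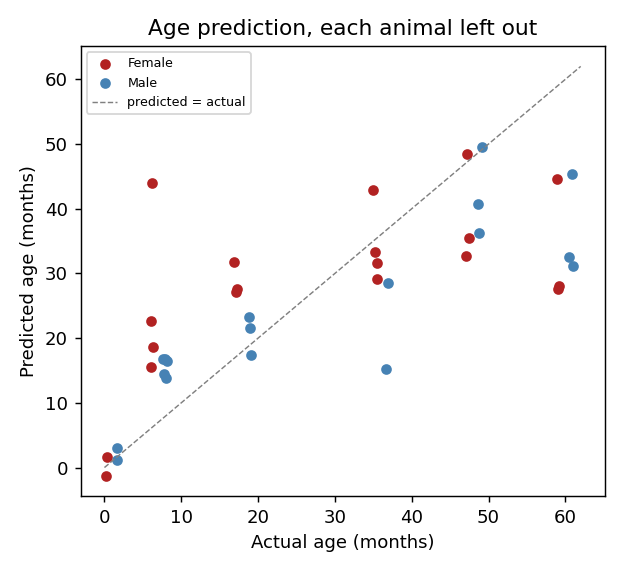
Predicted against actual age in months of 37 animals, each predicted from a model trained on the others, females red and males blue, with a dashed line where both are equal. One female of 7 months was predicted at 44.0 months.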

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

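The tests of enzymatic conversion, of a whole-methylome shift in males, of calls among animals of 7 months and over and the 3 tests at 62450001 to 62568000 of scaffold_7 were chosen only after the result was seen. So were the results on the wider set of windows, although the tests run on it had been written down beforehand.

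The site at 194704058 of scaffold_3 stood out because its change with age differed between the sexes by 89.277 points, tested by the interaction term in 32 animals. Chance was not excluded for this call: of 50 arrangements of sex within ages, the real one included, 3 gave at least 1 site, and the highest other gave 2.

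Within groups of 4 to 10 animals, 15 groups of values were searched for an animal far from the rest, and 3 were found. Chance marks about 1 in 20 such groups. The female 7mo Female replicate 5 had a level of rising minus falling windows of 22.545 points, where the other 3 females of 7 months lay between 5.10 and 7.04; a wrong age label of this animal was not tested and is not excluded, and without it the count of windows called in females was 13 in place of 1 and the sex difference of predicted age -1.74 months in place of -4.26. The library of 7mo Female replicate 3 had 15,372,466 cytosines with a value, against 10,022,656 to 10,839,718 in the other 3. In 36mo Female replicate 4 the mean entropy was 0.557 bits, against 0.503 to 0.512 bits in the other 3.

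More windows rose than fell with age, but less complete enzymatic conversion in libraries of older animals is argued against: it would raise unmethylated windows most, by about 10.8 points from what the windows over 60% showed, but the 2,192 windows under 5% methylated changed by a median of 0.358 points. Other faults of the enzymatic steps were not tested. The number of cytosines per library does not account for the rise in mean level either, since its partial correlation with age given that number was 0.515 (permutation p = 0.00085). The 1 month animals alone are argued against as the whole cause of the calls with age. Among the 33 animals of 7 months and over 22 windows were called, 17 rising and 5 falling. Of 50 arrangements of the ages, the real one included, the highest other called 0, so they cannot test whether rises outnumber falls. Without the 1 month animals, 226 windows of the wider set rose and 182 fell, and mean methylation had r = 0.0880 with age (permutation p = 0.634). Whether the 1 month animals account for the excess of rises therefore stays open. In windows picked by comparing 1 with 7 months, the level of rising minus falling windows had r = 0.347 with age among 24 animals of 18 months and over (permutation p = 0.0983), which decides nothing by itself. The same test on the wider set gave r = 0.677 (permutation p = 0.00034), which argues against the 1 month animals as the whole cause of the calls there too. Falling windows alone can raise this level, so it does not test the excess of rises. A change of blood cells with age, which the design names, or of the cell types in the pellet may also underlie the rises, and neither was tested.

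The windows between 62450001 and 62568000 of scaffold_7 were lower in males. The lowest female value, 80.64%, lay above every male value in the 35 denser libraries, so the difference did not rest on single animals. The windows were picked for their sex difference, which favours such a separation, so it does not test an effect of coverage. Reads of a second male copy, such as one on the Y, placed here may account for it: each animal's share of cytosines with a value in the span, over its share in the rest of the segment, averaged 2.14 ± 0.377 in males (SD, n = 17) and 1.29 ± 0.145 in females (SD, n = 18), a ratio of 1.654, and the ratio formed from the mean shares was 1.59. A first measure, male over female sites per tested window, had pointed the other way, and the measure was changed after that had been seen. It was 0.715 over the 11 windows from 62178001 to 62568000, which reach beyond this place, against 0.861 in the rest. The measures thus do not cover the same span, and no value decides which of them is the better one. A second copy beside an X copy held at the female level is argued against as the whole cause, since 30.3% of 304 cytosines over 80% in females lay under 20% in males, and a sex difference on the X itself stays open.

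The 16 windows outside the segment were lower in males. A shift of the whole methylome by the same amount is argued against as the whole cause, because the median difference of windows outside the segment was only -0.41 points. Centring each animal could therefore remove little: each of the 16 kept at least 86.7% of its difference, and 14 of them were still called. Reads of sex-linked copies may account for part of these windows: males had a median of 1.192 times the female number of sites, outside the range of 0.965 to 1.05 from 10,000 random sets. Single windows ran from 0.991 to 2.11. The window with the largest difference, at 34889001 of scaffold_10, had 1.021. Those at 10034001 and 10035001 of scaffold_11 had 0.991 and 1.034, that at 202764001 of scaffold_3 had 1.01 and that at 16272001 of scaffold_4 had 1.009. The other windows had 1.113 or more. On the wider set the 23 called windows had a ratio of 1.034, inside their range of 0.962 to 1.06, and 11 of the 16 windows were among them. A difference of sex itself stays open.

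For the other counts, real labels were set against shuffled labels in 50 arrangements each, the real one included. Chance is argued against where no shuffled arrangement reached the real count. This held for windows and age (306 called, highest other 3), windows and sex (16, highest other 1), and windows and age in males (21, highest other 1) and in females (1, highest other 0). It also held for sites and age (2, highest other 0) and sites and sex (122, highest other 1). The smallest share that 50 arrangements can give is 1 in 50, not adjusted over these counts, so chance is not excluded. The count of 1 window in females and that of 2 sites with age fell to 0 without some single animals. For the 0 windows of the interaction and the 0 sites within females and within males, all 50 arrangements give at least as many whatever they call, so this comparison decides nothing on chance there; the highest other was 1 each.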

How the results depend on the processing

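All settings without the sparse libraries, on the arcsine scale, with centring, with sites in at least 20 animals, with deviations from site means, with windows in at least 34 animals, with the wider set, with other site sets, the plain mean or no 1 month animals for the global measures, without other pairs of 60 month animals, with all windows for the age prediction or given the number of cytosines were chosen only after the result was seen. No paired analysis was possible because the replicate numbers name different animals in each group. Kinship among the animals was not given in the sources used here, and the tests treat them as independent. A minimum of 10 reads, no minimum, weighting by reads, thinning to 5 reads, the count model with either dispersion, and anything that needs gene positions were not run, and prediction with 20,000 windows was possible only without the sparse libraries. Where no cause is named, the cause was not tested. Over all results and other settings, 95 comparisons kept direction and side of the threshold, 30 became stronger, 29 weaker and 3 reversed. For named sites and windows, 547 kept both and 95 lost the call.

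For sites and age (2 called), log2 age gave 132, of which 96 rose where both had fallen, sites in at least 20 animals 1,176, centring 4, the arcsine scale 5, no sparse libraries 1, no filter on the mean 1, and unmoderated variances, no 1 month animals, no 60 month animals and sites in all animals 0 each. Without single animals it was 0 to 4. For sites and sex, sites in all animals gave 7. For the interaction at sites (1 called), log2 age, no 1 month animals, sites in all animals and sites in at least 20 gave 0, no 60 month animals 2, and single animals left out 0 to 3. For sites in females (0 called), log2 age gave 33, unmoderated variances 7, sites in at least 20 animals 1 and single animals left out 0 to 2, with 2 without 60mo Female replicate 2. For sites in males (0 called), log2 age gave 4, unmoderated variances 1, no 60 month animals 3, centring 2, no filter on the mean 1, sites in at least 20 animals 4 and single animals left out 0 to 1, with 1 without 18mo Male replicate 1 or 60mo Male replicate 2.

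For windows and age (306 called), log2 age gave 1,092, a change of at least 10 points 180, no 1 month animals 22, no 60 month animals 127, no sparse libraries 661, centring 115, deviations from site means 484, windows in at least 34 animals 2,182, the wider set 4,814 and at least 10 sites 115, where 8,286 windows were left. Single animals left out gave 159 to 396. Of the 306 windows, 277 were also called on log2 age and 250 in the wider set. For windows and sex (16 called), a change of at least 10 points gave 5, no 60 month animals 9 and windows in at least 34 animals 27. The interaction at windows gave 0 under every setting run.

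For windows in females (1 called), log2 age gave 293, windows in at least 34 animals 4, of which 3 fell, the wider set 52, and unmoderated variances, no 1 month animals, no 60 month animals, no sparse library and deviations from site means 0 each. The call was lost without 1mo Female replicate 2, 7mo Female replicates 2, 3 and 4, 18mo Female replicate 1, 36mo Female replicates 1 and 3, 48mo Female replicates 1, 3 and 4, or 60mo Female replicates 1 and 3, each left out alone. It was 2 without 18mo Female replicate 2 or 36mo Female replicate 4, 3 without 18mo Female replicate 3, and 13 without 7mo Female replicate 5, so it ran from 0 to 13.

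For windows in males (21 called), log2 age gave 75, unmoderated variances 7, no 1 month animals 5, no 60 month animals 11, the arcsine scale 52, centring 12, deviations from site means 79, windows in at least 34 animals 171, the wider set 519 and at least 10 sites 13. It was 3 without 1mo Male replicate 1 or 7mo Male replicate 5, 4 without 1mo Male replicate 2 or 7mo Male replicates 2 or 3, 5 without 60mo Male replicate 1 or 7mo Male replicate 1, 6 without 48mo Male replicate 3 or 7mo Male replicate 4, 10 without 48mo Male replicate 1, 11 without 60mo Male replicate 3, 12 without 18mo Male replicate 1, 33 without 18mo Male replicate 3 and 40 without 48mo Male replicate 2.

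For mean methylation and age, r came past the threshold with sites in at least 20 animals (0.344), the plain mean of each animal (0.330), no sparse libraries (0.565) and given the number of cytosines (0.515), was 0.0676 with all sites of each animal, and ran from 0.220 to 0.430 without single animals. The sex difference of mean methylation stayed short of the threshold under every setting run, from -1.35 points with all sites of each animal to -0.142 without 36mo Male replicate 1. For entropy and age r no longer passed without the 1 month animals (-0.290). The sex difference of predicted age reversed on log2 age (0.265) and ran from -5.14 to -1.74 months without single animals; it was -1.71 without the sparse libraries and -1.49 with deviations from site means. The prediction error ran from 7.48 to 10.1 months without single animals, and was 12.2 months with ridge regression and 3.71 months on log2 age. A value in all 37 animals was present at 70,377 autosomal sites, and the effect of the unknown read depth could not be assessed.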

Other observations

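The scan for coverage gaps was chosen only after the result was seen.

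The wider set of 165,131 windows, an added alternative, gave a fuller view of where methylation fell with age. There 4,814 windows were called by the limma test, 3,709 rising and 1,105 falling. With each animal centred on its own median shift, 2,499 windows of this set were called, 846 rising and 1,653 falling, so that the balance turned. Without the 1 month animals 408 were called, 226 rising and 182 falling. Of windows between 20 and 60% methylated 9.20% were called and 40.3% of these calls rose, so that falls outnumbered rises in that class, where the stricter windows had 54.7% rising. Of windows over 80% methylated 1.73% were called, and 97.3% of these rose. Falling windows averaged 55.8% ± 1.69 at 1 month (SD, n = 4), 45.6% ± 2.97 at 7 months (n = 9) and 34.2% ± 1.48 at 60 months (n = 5), in windows picked for their relation with age. The group of windows lower in males on scaffold_7 held 24 called windows there, from 62448001 to 62590000, all lower in males, and the rest of the segment held 33, of which 31 were lower in males.

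Windows with more than 80 cytosines per kb that were under 20% methylated, 1,749 in all, rose in 35 cases and fell in 0. Those under 20% with fewer than 41 cytosines per kb rose in 15 and fell in 7 of 197. In the wider set the latter class rose in 47 and fell in 115 of 1,475, the opposite balance.

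The female 7mo Female replicate 5 was predicted at 44.0 months, while the other 3 females of 7 months were predicted at 15.5 to 22.6 months. Its share of cytosines with a value in the scaffold_7 segment relative to autosomes, 1.36, was the highest of the females, followed by 1.34 in 48mo Female replicate 1. On the rest of scaffold_7 their shares were also high, 1.11 and 1.13. The female mean there was 0.940 in the denser libraries, so the excess was not particular to the segment.

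In 14 libraries, 32 stretches of at least 10 Mb had fewer cytosines with a value than the median library, at a ratio under 0.75. Several shared an edge. On scaffold_1, the stretch from 343,000,001 to 356,000,000 was low in 1mo Female replicate 1 (0.561), 7mo Female replicate 3 (0.548), 7mo Female replicate 4 (0.506) and 7mo Male replicate 2 (0.580).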
